A study of Mus musculus with 2 samples.

How the data were processed

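Single-cell RNA sequencing of whole mouse aorta, from the arch to the bifurcation, was compared between 2 groups with 1 library each. Per the labels, the mice were male, of the C57BL6 background, and carried a floxed Cept1 genotype in both groups. The overexpression group also carried a tamoxifen-inducible Cre recombinase under the promoter of VE-cadherin, an adhesion molecule of endothelial cells, and the control group lacked Cre. Tamoxifen was given as 5 daily injections of 1 mg from an age of at least 8 weeks, followed by 5 days of recovery, per the labels' protocols; the age label itself gives 6 to 8 weeks. Aortic tissue (n = 3 per condition, per the labels' protocols) was digested with enzymes, strained and treated to lyse red cells before 10x Genomics 3′ v3 capture. Whether the tissue of the 3 mice was pooled, and which gate the mentioned sort used, is not given in the sources used here. The groups below are called the Cept1 library and the control library.

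The deposited values are raw UMI counts per gene and cell barcode, whole numbers with no normalization, made with Cell Ranger 7.2.0 per the file headers. The submitters' processing notes name Cell Ranger, Seurat and the mm10 build. The gene annotation, the counting of intronic reads, the use of strand and any step taken with Seurat are not given in the sources used here. The deposited counts covered 32285 features, of which 32158 identifiers (99.6%) were found in GENCODE vM21 on GRCm38, which gave the coordinates; 38 symbols were duplicated. In both libraries the lowest barcode total was 500 UMIs. Of the 17728 and 14349 barcodes in the Cept1 and control libraries, 11168 and 8729 had at least 500 genes and at most 10% mitochondrial UMIs.

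Doublets were scored in each library with Scrublet (scanpy 1.11.5, expected rate 8%). Its automatic threshold was 0.245 in the Cept1 library and 0.744 in the control library, where it called 1 cell. The threshold of the Cept1 library was therefore used in both, a choice made after the scores were seen, and it removed 486 cells (4.35%) and 89 cells (1.02%). The kept 10682 and 8640 cells were clustered jointly on 2000 variable genes, 30 principal components and 20 neighbours by the Leiden method at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, seed 1). Each of the 35 clusters was called by the fixed marker set with the largest share of its genes among the cluster's 100 leading genes, with at least 2 leading and 3 detected markers. A cluster stayed unnamed where another class had more markers among its top 10 genes, or where its median depth was below the library median divided by 3 with none of its own markers there; this left 4 clusters unnamed. Leading genes were ranked by fold over the median of the other clusters. This replaced a ranking against all other cells after fibroblast clusters had stayed unnamed under it.

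For each class, UMIs were summed over the cells of a library and divided by all UMIs of that class. Ratios are given as log2 of the Cept1 library over the control library with exact 95% Clopper-Pearson intervals of the split of a gene's UMIs, and shares of cells with exact 95% binomial intervals. These intervals cover counting error only. With 1 library per group no test between groups was possible, cells were not used as replicates, and no p-value was computed. A gene with 0 UMIs in a library has an upper limit of 3 counts.

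Gene lists, cell type markers, the rule for named genes and most alternative settings were fixed before the data were examined. There were 20 lists: PPARα targets, VEGF signalling, phospholipid synthesis, PPAR family and partners, tip cell and angiogenic growth, Notch and arterial endothelium, endothelial inflammation, shear response and nitric oxide, endothelial to mesenchymal transition, sterol and fatty acid synthesis, unfolded protein response, glycolysis and hypoxia, oxidative phosphorylation, immediate early and dissociation genes, interferon response, extracellular matrix and basement membrane, smooth muscle contraction, cell cycle, endothelial lipid handling, and free RNA and other cells. A list's value is the median log2 ratio over members with at least 20 UMIs in the class, with a 95% interval from 1000 Poisson redraws of the counts. Its percentile among 10000 random lists of the same size and expression describes these libraries and is not a test. The named genes were Cept1, Ppara, Vegfa, Kdr and Flt1; the 12 highest and 12 lowest ratios in endothelial cells among genes with at least 100 UMIs there; the 4 measured members of each list with the largest change; and the 5 highest and 5 lowest in each other class with at least 100 cells per library, among genes with at least 200 UMIs. The highest and lowest sets left out mitochondrial, ribosomal protein and haemoglobin genes, immunoglobulin and T cell receptor segments, and unnamed gene models. They also left out genes whose level in the class, in the library where it was higher, was below 0.5 of that in all other kept cells. A result for 1 gene that this rule names is not reported here.

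The ratio and list procedures were tested on simulated data for the endothelial comparison over 10464 genes. Direction was recovered for 100% of 100 genes changed 1.5-fold and 100% of 100 genes changed 2-fold. The interval covered the true ratio for 97.0% and 99.0% of them and for 95.6% of 10264 unchanged genes. A list of 30 changed genes had a median of 0.74 and a list of 30 unchanged genes 0.02. The counts were Poisson draws around a shared profile, as the intervals assume, so this checks the calculation under counting error only. Differences between mice, cluster mix, doublets and free RNA were not simulated. Alternatives fixed in advance were stricter and looser cell filters, doublets kept, resolutions 0.5 and 2, a marker gate without clustering, edgeR 4.0.16 TMM scaling, a total without mitochondrial, ribosomal protein and haemoglobin genes, subtraction of an estimated free RNA share, cells thinned to 2000 UMIs, equal weight per cell, and other count minimums for list members. Thinning left out 32 and 48 endothelial cells below 2000 UMIs in the Cept1 and control libraries. Each endothelial cluster alone, equal weight per cluster, addition of a shallow endothelial-led cluster, removal of the 5% highest doublet scores of each library, and removal of cells with adipocyte marker UMIs were chosen after seeing the data. The other steps used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15.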

Results

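Whole aorta of adult male mice with endothelial overexpression of Cept1 was compared with that of Cre-negative controls by droplet-based single-cell RNA sequencing, which counts unique molecular identifiers (UMIs) per gene and cell. Cept1 encodes choline/ethanolamine phosphotransferase, an enzyme of the last step in the synthesis of phosphatidylcholine and phosphatidylethanolamine. The title of the series places the question in angiogenesis, the nuclear receptor PPARα and the growth factor VEGF-A. Each group held 1 library, so differences have no replicate check, none was tested, and intervals cover counting error only. The Cept1 library held 95735360 UMIs over 17728 barcodes and the control library 88220524 UMIs over 14349 barcodes. After filtering, 10682 and 8640 cells remained, with medians of 6305.5 and 6720 UMIs and of 2489 and 2497 genes per cell. Levels are UMIs scaled to a common total per library and class (CPM), and log2 ratios are those of CPM, the Cept1 library over the control library, with 95% intervals where given.

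Endothelial-like cells made up 11.6% of kept cells in the Cept1 library (1234 cells, interval 11.0 to 12.2%) and 7.58% in the control library (655 cells, 7.03 to 8.16%), a difference of 3.97 percentage points. Fibroblast-like cells were the largest class with 50.4% and 43.9%, and macrophage-like cells made up 16.0% and 10.6%. T or NK-like cells were lower in the Cept1 library, at 3.11% against 8.33%, and so were B-like cells, at 1.95% against 6.90%. Smooth muscle-like cells made up 6.67% and 7.23%, lymphatic endothelial-like cells 2.26% and 1.75%, monocyte or dendritic-like cells 2.69% and 2.47%, and neutrophil-like cells 1.25% and 1.76%. Smaller classes were Schwann or neural-like cells (0.646% and 1.08%), mast-like cells (0.393% and 0.451%), mesothelial-like cells (0.346% and 0.660%) and plasma-like cells (0.066% and 0.324%). Unnamed clusters held 2.68% and 6.99%, including a shallow cluster led by endothelial genes with 0.824% and 2.26%. The endothelial difference was 1.96 points with at least 1000 genes and at most 5% mitochondrial UMIs per cell, and 2.54 points with the shallow cluster added. Dissociation, the sort named in the labels and its unstated gate also enter these shares. Among T or NK-like cells, cluster 11, led by Lef1, held 1.24% and 5.67% of kept cells. Cluster 24, with Themis and Rag1 among its top 10 genes, held 0.421% and 1.15%. Whether all lymphoid cells came from the aortic wall was not tested.

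**Figure D1:**
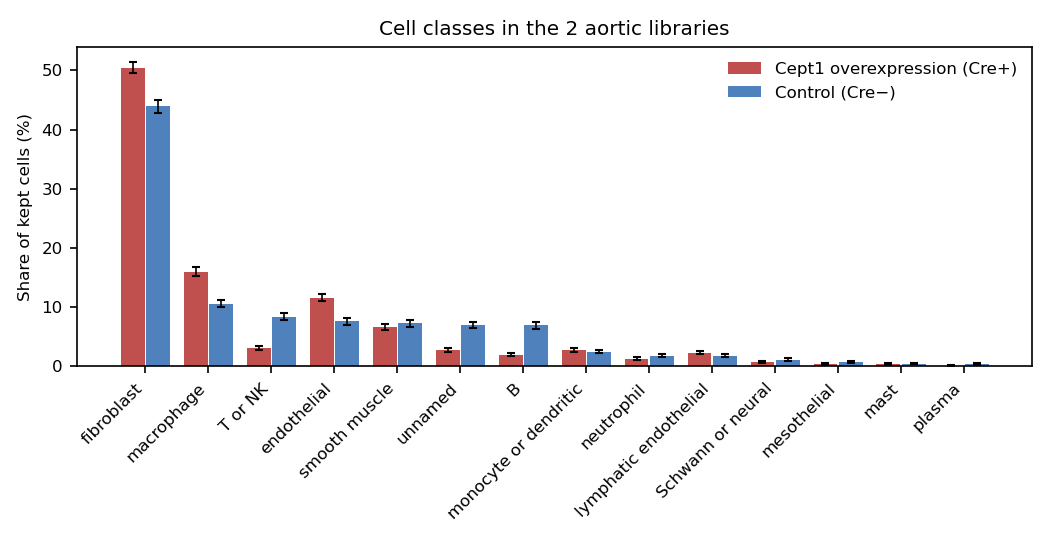
Share of kept cells (%) in each cell class for the Cept1 overexpression and control libraries, as bars with exact 95% binomial intervals that cover counting error only. Endothelial-like cells were at 11.6% and 7.58%, and T or NK-like cells at 3.11% and 8.33%.

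The endothelial class consisted of 3 clusters in different proportions in each library, and pooled endothelial values mix them. Cluster 7, led by Cytl1, Gkn3 and Bmp6 and by the arterial genes Bmx and Gja5, held 63.5% of endothelial-like cells in the Cept1 library and 41.5% in the control library. Cluster 12, led by the lipid uptake genes Fabp4, Gpihbp1 and Cd36 and by Kdr, held 27.6% and 37.3%. Cluster 18, led by Lrg1, Vwf, Emcn and Plvap, held 9.0% and 21.2%. A gene of cluster 12 or 18 can therefore have a lower pooled value with no difference inside any cluster. Inside cluster 7 alone 13 of 92 named genes had the opposite sign to the pooled value, inside cluster 12 alone 18 of 95 and inside cluster 18 alone 31 of 80. Values with the 3 clusters weighted equally are given where they turn a direction.

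Cept1 itself (ENSMUSG00000040774, minus strand of chromosome 3, 106502260 to 106547802, GRCm38) was 1.62-fold higher in endothelial-like cells of the Cept1 library (log2 0.70, interval 0.55 to 0.85). The levels were 124.7 and 76.8 CPM, from 1240 and 513 UMIs. The ratio was 0.73 in cluster 7 and 0.96 in cluster 12, and in cluster 18 it was 0.05 (-0.39 to 0.49). All other kept cells together were at 0.28 (0.22 to 0.34). Among them monocyte or dendritic-like cells were at 0.40 (0.13 to 0.67), T or NK-like cells at 0.33, smooth muscle-like cells at 0.29, macrophage-like cells at 0.25, fibroblast-like cells at 0.12 and B-like cells at -0.10 (-0.52 to 0.30). The other kept cells also included lymphatic endothelial-like cells (241 in the Cept1 library and 151 in the control library). They included the shallow cluster led by endothelial genes as well. The value of 0.28 is therefore not that of cells free of endothelial types. The lymphatic endothelial-like value is shown only in the plot of Cept1 ratios by class. The annotated gene overlaps Dennd2d and Dram2 on the other strand. Whether the overexpressed transcript carries the endogenous 3′ end that the assay counts is not given in the sources used here.

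The gene with the lowest ratio in endothelial-like cells was Gt(ROSA)26Sor, the transcript of the Rosa26 locus that is widely used for inserting transgenes (chromosome 6, 113067428 to 113077333, minus strand). It had 8 UMIs in the Cept1 library and 172 in the control library (log2 -5.00, -6.24 to -3.99). Low values were not limited to the endothelium: fibroblast-like cells were at -4.89 (-5.63 to -4.23), smooth muscle-like cells at -5.44 (-7.33 to -4.07) and T or NK-like cells at -4.03 (-5.49 to -2.89). Macrophage-like cells were at -2.11 (-2.41 to -1.82), monocyte or dendritic-like cells at -0.66 (-1.19 to -0.15) and neutrophil-like cells at -0.07 (-1.46 to 1.24). The annotated gene overlaps Thumpd3 on the other strand. The labels give the same floxed Cept1 genotype for both groups and do not name the locus of the overexpression allele.

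**Figure D2:**
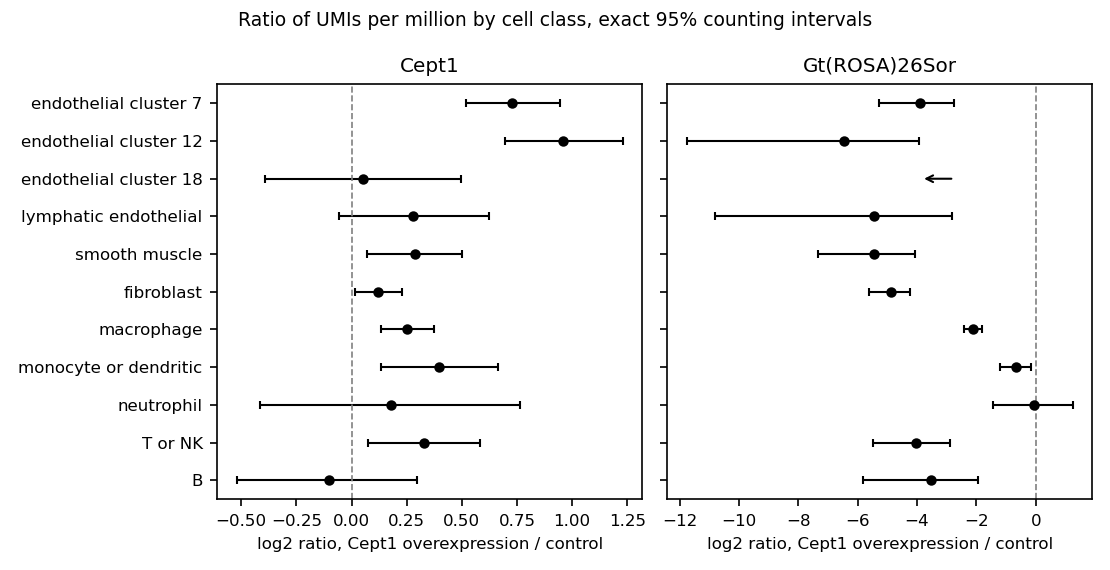
Log2 ratio (Cept1 overexpression over control) of Cept1 and of Gt(ROSA)26Sor in CPM, as points with exact 95% counting intervals. Rows are the endothelial clusters and the other classes with at least 100 cells per library. An arrow marks an upper bound where the Cept1 library had 0 UMIs. Cept1 was at 0.73, 0.96 and 0.05 in endothelial clusters 7, 12 and 18. Gt(ROSA)26Sor was at -4.89 in fibroblast-like cells and at -0.07 in neutrophil-like cells.

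PPARα is a nuclear receptor that drives fatty acid oxidation genes. Its gene Ppara (chromosome 15, 85734983 to 85802819) was too sparse to compare, with 19 and 7 UMIs in endothelial-like cells (log2 0.87, -0.45 to 2.36). The PPARα target list was slightly lower in the Cept1 library, with 13 of 40 measured members higher, 27 lower and a median of -0.10 (-0.18 to -0.04), at the 3.06 percentile of matched random lists. With at least 1000 genes and at most 5% mitochondrial UMIs per cell, it was at -0.004 (-0.08 to 0.06). Acsl1, which activates long-chain fatty acids, was at 0.60 (0.32 to 0.89), the lipoprotein lipase gene Lpl at -0.56 (-0.65 to -0.48), Fabp3 at -1.66 (8 and 17 UMIs) and Cpt1b at -0.65 (-1.63 to 0.33). Lpl was at 0.07 in cluster 12 and 1.02 in cluster 18. The direction turned by cluster. In cluster 12 alone, defined in part by the members Fabp4 and Cd36, the list was at 0.16 (0.09 to 0.27). There 25 of 36 members were higher and 11 lower, at the 99.28 percentile of matched random lists. With equal cluster weights the list was at -0.03. Acsl1 was at -0.36 with every cell weighted equally. In cluster 12 it was at 1.94 (192 and 61 UMIs) in cells with adipocyte marker UMIs and at 0.45 (-0.06 to 0.97) in cells without them. In cluster 7 cells without them it was at -0.07 (-0.70 to 0.59). The list member Angptl4 was at 1.17 (0.86 to 1.48, from 301 and 126 UMIs) in cluster 12 cells without adipocyte marker UMIs. It was at 0.93 in cluster 12 cells with them, and at -0.09 (-1.20 to 1.10) in cluster 7 cells without them. The PPAR family and partners list was at -0.03 (7 of 15 higher), and at 0.03 with equal cluster weights. Its member Ppargc1a, a coactivator of mitochondrial genes, was at 0.91 (0.03 to 1.87; 42 and 15 UMIs), Nr1h3 at -0.63 (-1.06 to -0.21) and Ppargc1b at -0.47 (-1.28 to 0.34). Nr1h3 was at 0.07 under the marker gate.

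Vegfa, the gene of VEGF-A (chromosome 17, 46016993 to 46032369), was at 0.17 in endothelial-like cells (-0.02 to 0.37; 576 and 343 UMIs), with an interval that includes 0. It was at 0.44 (0.19 to 0.69) in cells chosen by a marker gate without clustering, 0.22 (0.02 to 0.41) with TMM scaling and 0.24 (0.05 to 0.43) with the shallow cluster added, and at -0.02 (-0.23 to 0.19) without cells that held adipocyte marker UMIs. Its value differed by cluster, at -0.30 (-0.51 to -0.08) in cluster 7, 1.54 (0.90 to 2.22; 78 and 28 UMIs) in cluster 12 and -0.59 (-1.51 to 0.28) in cluster 18. In monocyte or dendritic-like cells Vegfa was at 1.21 (0.83 to 1.60), and its values in the other classes are not given here. That value also compares clusters, since cluster 19 held 171 and 73 of these cells and cluster 20 held 107 and 127. The VEGF receptor genes Kdr and Flt1 (chromosome 5, 75932827 to 75978458 and 147561604 to 147726011) were at -0.42 (-0.50 to -0.34) and -0.61 (-0.67 to -0.55) in the pooled class. Kdr, which helps define cluster 12, was at 0.06, 0.19 and 0.47 inside clusters 7, 12 and 18, and at 0.23 with equal cluster weights. Flt1 was at -0.29, -0.02 and 0.02 inside the same clusters. The VEGF signalling list had 13 of 44 members higher and a median of -0.13 (-0.18 to -0.07), at the 0.06 percentile, but 0.02 with equal cluster weights and -0.05 (-0.11 to -0.002) under the same stricter cell filter. Its members with the largest changes were Nfatc2 (-1.03), Prkcb (-0.70), Flt1, and Flt4, the VEGF-C receptor gene (-0.46). Nfatc2 was at 0.38 with doublets kept, and Prkcb and Flt4 were at 0.36 and 0.13 in cells chosen by a marker gate without clustering.

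Phospholipid synthesis genes showed no common increase. Of 40 measured members, Cept1 among them, 16 were higher and 24 lower, with a median of -0.12 (-0.18 to -0.02) at the 2.95 percentile, and -0.05 with equal cluster weights. After Cept1 the members with the largest changes were Etnk2 (-0.57, -1.52 to 0.37), Mboat2 (-0.52, -1.08 to 0.04) and Mboat1 (0.51, -0.36 to 1.43), each with an interval across 0. With equal cluster weights Etnk2 was at 0.07 and Mboat2 at 0.33. In cluster 18 alone the list was at 0.05.

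Of 9136 genes ranked in endothelial-like cells, the 12 highest included Thbs1, the gene of the antiangiogenic matrix protein thrombospondin-1. It was 2.39-fold higher (log2 1.26, 1.19 to 1.32; 8564 and 2406 UMIs) and higher inside all 3 clusters (0.79, 1.77 and 1.39). The Wnt inhibitor gene Frzb was at 1.51, and the growth factor genes Gdf6, Nrg1 and Ereg were at 1.78, 1.58 and 1.58. These 4 had nearly all of their UMIs in cluster 7, where they were at 1.09, 1.34, 1.36 and 1.15; Ereg was at -0.03 with equal cluster weights. Prr16 (1.39) and Gna14 (1.25) were also among the highest. The adipocyte genes Cfd (2.21; 1645 and 239 UMIs) and Adipoq (2.11; 90 and 14 UMIs) and the cytochrome gene Cyp2e1 (1.88) had nearly all of their UMIs in cluster 12. In all other cells Cfd was at -1.54 and Adipoq at -1.20. Adipoq was at -0.15 with every cell weighted equally, and Cyp2e1 at -0.10 without cells that held adipocyte marker UMIs and at -0.20 with at least 200 genes and at most 20% mitochondrial UMIs. The platelet genes Ppbp (2.27) and Nrgn (1.47) were also higher in all other cells, at 1.69 and 1.29.

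Besides Gt(ROSA)26Sor, the lowest ratios were those of Lsmem1 (-3.46; 16 and 118 UMIs) and Cxcl10 (-2.64; 154 and 644 UMIs), the gene of an interferon-induced chemokine. Lsmem1 was lower inside all 3 clusters. Cxcl10 was at -4.81 in cluster 7 (42 and 563 UMIs), and at 0.69 and 0.46 in clusters 12 and 18. Igfbp3 (-1.90) and Prnd (-1.89) had most of their UMIs in cluster 12, where they were at -1.42 and -1.23. Hey1, a Notch target, was at -1.63 (98 and 204 UMIs) and lower inside all 3 clusters (-0.79, -1.39 and -1.22). The others were Egfem1 (-2.39), Wdr17 (-1.85), Nup210l (-1.67), Alpl (-1.61), Robo2 (-1.55) and the leptin receptor gene Lepr (-1.45). Egfem1 was at 0.26 in cluster 7, Wdr17 at 1.06 in cluster 12, Igfbp3 at 0.42 in cluster 18 and Alpl at 0.03 with equal cluster weights.

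Angiogenic growth genes were lower in the pooled endothelial class of the Cept1 library. The tip cell and angiogenic growth list had 8 of 34 members higher and a median of -0.29 (-0.31 to -0.20), and -0.09 with equal cluster weights. Esm1, a tip cell gene with UMIs in cluster 12 only, was at -2.37 (13 and 45 UMIs), the adrenomedullin gene Adm at -0.97 and the apelin receptor gene Aplnr at -0.81. The Notch and arterial list was higher, with 12 of 22 members higher and a median of 0.12 (0.05 to 0.19), but at -0.06 with equal cluster weights. Its members with the largest changes were all lower: Hey1, Jag2 (-0.85), Sema3g (-0.78) and Dll4 (-0.73). Sema3g was at 0.07 with equal cluster weights. The shear response and nitric oxide list was at -0.05 (-0.09 to 0.03; 8 of 19 higher), with the prostaglandin synthase gene Ptgs2 at 1.02 (0.66 to 1.39) and higher inside all 3 clusters. In the same list the arginine transporter gene Slc7a1 was at 0.55, the endothelin gene Edn1 at 0.47 and Gucy1a1 at -0.54. Edn1 was at -0.19 with equal cluster weights, Gucy1a1 at 0.80 with cells thinned to 2000 UMIs and Slc7a1 at -0.03 in cluster 12.

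**Figure D3:**
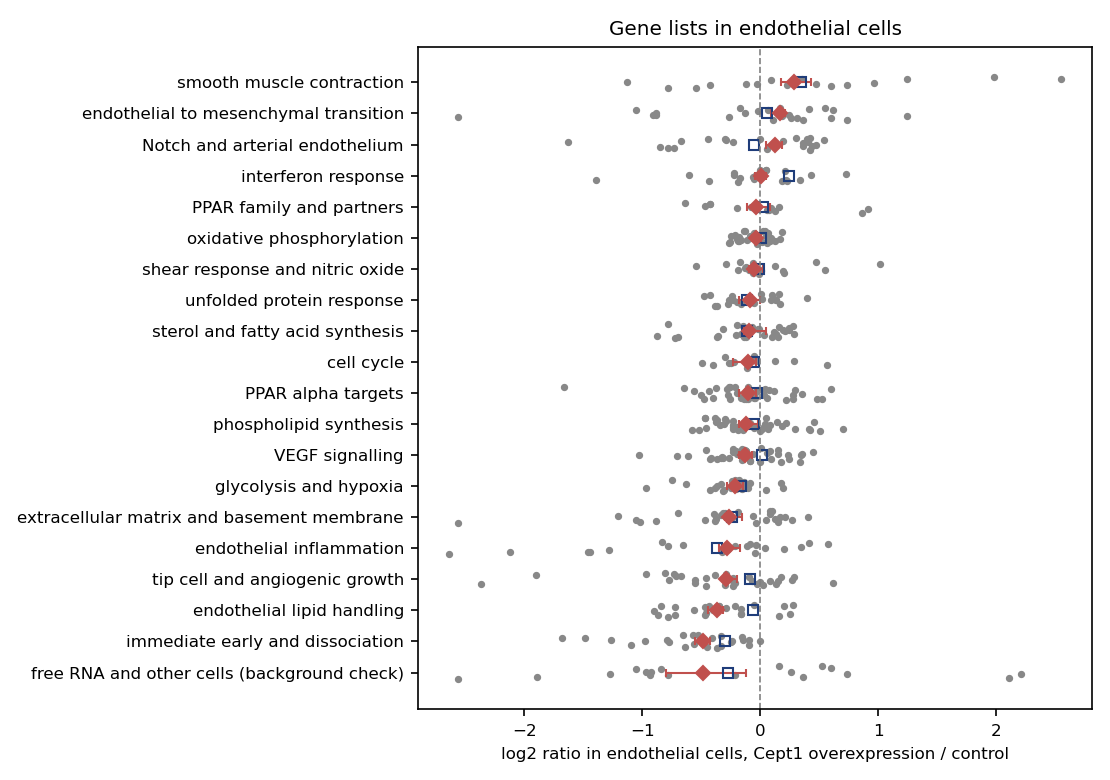
Log2 ratio (Cept1 overexpression over control) in endothelial-like cells for the measured members of each gene list, with grey points for members, red diamonds for the pooled median with its 95% interval from Poisson redraws, and open blue squares for the median with the 3 clusters weighted equally. The immediate early list was at -0.49 and the smooth muscle contraction list at 0.29; the VEGF signalling list was at -0.13 pooled and at 0.02 with equal weights.

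Inflammatory and immediate early genes were lower in the pooled endothelial class of the Cept1 library. The endothelial inflammation list had 5 of 22 members higher and a median of -0.28 (-0.35 to -0.17), with the chemokine genes Cxcl2 at -2.12 and Ccl2 at -1.45, the cytokine gene Il6 at -1.46, and Cxcl10 as above. The list of free RNA and other cells was also lower in these cells (-0.49). The estimated free RNA share was 4.55% in the Cept1 library and 9.98% in the control library. This estimate rests on markers of other cells in endothelial-like cells and not on empty droplets, so doublets and class mix also enter it. With doublets kept, the inflammation list was at 0.01, Cxcl2 at 1.29 and Ccl2 at 0.89. The inflammation list was at -0.10 (-0.21 to 0.04) in cluster 7, -0.53 in cluster 12 and -0.15 in cluster 18. It was also lower in fibroblast-like (-0.22), macrophage-like (-0.31), monocyte or dendritic-like (-0.36) and smooth muscle-like cells (-0.06). In T or NK-like (1.09), neutrophil-like (0.76), B-like (0.14) and lymphatic endothelial-like cells (0.045) it was higher. The immediate early and dissociation list, which also reacts to tissue digestion, had 1 of 24 members higher and a median of -0.49 (-0.55 to -0.43), against -0.16 in fibroblast-like cells (4 of 24 higher), 0.88 in T or NK-like cells and 0.13 in all other cells pooled. Fosb was at -1.49, Socs3 at -1.26, Fos at -1.10 and Egr2 at -1.68 (32 and 69 UMIs; 0.12 with doublets kept). The list was at 0.06 in cluster 7, -0.49 in cluster 12 and -0.55 in cluster 18. The interferon response list was at 0.01 (13 of 25 higher), with Isg15 at -1.39, Ifit1 at 0.73, Rsad2 at -0.61 and Irf7 at -0.44. It was at -0.15 (-0.20 to -0.08; 7 of 25 higher) in cluster 7, 0.03 in cluster 12, 0.53 (0.38 to 0.61; 22 of 24 higher) in cluster 18 and 0.24 with equal cluster weights. Rsad2 was at -3.14 in cluster 7 and 5.28 in cluster 18, Irf7 at -0.61 and 1.60, and with equal cluster weights they were at 0.56 and 0.27. In all other cells the interferon list was at 0.29, with 21 of 25 members higher.

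Metabolic lists moved little or downward. The glycolysis and hypoxia list had 3 of 24 members higher and a median of -0.21 (-0.28 to -0.14), with Adm as above, the lactate exporter gene Slc16a3 at -0.74, Egln3 at -0.63 and Pdk1 at -0.43. Egln3 was at 0.65 with equal cluster weights and Pdk1 at 0.11 with thinned cells. The glycolysis and hypoxia list was also lower in fibroblast-like (-0.21), macrophage-like (-0.24), smooth muscle-like (-0.18) and B-like cells (-0.26). It was at -0.01 in lymphatic endothelial-like, 0.075 in T or NK-like, 0.40 in neutrophil-like and 0.80 in monocyte or dendritic-like cells. Oxidative phosphorylation was at -0.04 (-0.07 to 0.01; 14 of 32 higher), with Atp5b, Cycs, Uqcrc2 and Atp5j between -0.26 and -0.21, and the list was at 0.01 with equal cluster weights. Endothelial lipid handling was lower, with 4 of 25 members higher and a median of -0.37 (-0.44 to -0.32), and -0.06 with equal cluster weights. Members of this list lead cluster 12. The phospholipid transfer protein gene Pltp was lower inside all 3 clusters (pooled -0.90), the transcription factor gene Tcf15 was at -0.86, Slc27a3 at -0.84 and Lrp1 at -0.78 (0.08 with free RNA subtracted). Sterol and fatty acid synthesis was at -0.09 (-0.14 to 0.05; 12 of 31 higher), with Sqle at -0.87, Lss at -0.79 and Cyp51 at -0.72, each from 41 UMIs or fewer in each library. The unfolded protein response list was at -0.09 (-0.18 to 0.00; 10 of 23 higher), with Ern1 at 0.40, Atf4 at -0.38, Trib3 at -0.42 and Chac1 at -0.47. The cell cycle list was at -0.10 (3 of 14 higher), with Top2a at 0.56 (-0.57 to 1.81), Tyms at -0.49, the cell cycle inhibitor gene Cdkn1a at -0.40 and Stmn1 at -0.30. Cdkn1a was at 0.38 with equal cluster weights.

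Genes of matrix and of other cell types also differed in endothelial-like cells. The extracellular matrix and basement membrane list had 10 of 28 members higher and a median of -0.26 (-0.30 to -0.15), with Col1a1 at -2.56 (581 and 2308 UMIs), Col15a1 at -1.21, Col3a1 at -1.05 and Sparcl1 at -1.02. In cluster 12 alone Col1a1 was at 0.25 and Col3a1 at 0.35. The endothelial to mesenchymal transition list was at 0.17 (0.09 to 0.21; 14 of 23 higher), with Col1a1, Col3a1 and Snai1 (-0.91) lower and Cnn1 (1.24; 67 and 19 UMIs) higher. The smooth muscle contraction list was at 0.29 (0.18 to 0.43; 10 of 16 higher), with Actg2 at 2.56 (35 and 4 UMIs), Myocd, a cofactor of smooth muscle transcription, at 1.99 (1.68 to 2.30), and Des at -1.13 (0.15 with equal cluster weights). Actg2 was at -0.83 under the marker gate and -0.72 in cluster 18. With at least 1000 genes and at most 5% mitochondrial UMIs per cell, the smooth muscle list was at -0.52, the endothelial to mesenchymal list at -0.002 (-0.07 to 0.07), Cnn1 at -1.20 and Snai1 at 0.06. The list of free RNA and other cells, which shares 5 of its 20 genes with other lists and of which 19 were measured in endothelial-like cells, was at -0.49 (-0.80 to -0.12; 8 of 19 higher), with Ucp1 at -1.90. It was at 0.19 with doublets kept and 1.57 with free RNA subtracted. The estimated free RNA shares are those given for the inflammatory genes.

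In fibroblast-like cells the progesterone receptor gene Pgr was at 4.36 (3.64 to 5.18; 343 and 16 UMIs), Stc1 at 2.32, Gal at 1.68, Dok6 at 1.49 and Sytl5 at 1.34. Coch (-2.76), Pde4c (-2.16), Vtn (-1.23) and Dact2 (-1.23) were lower, and Coch was at 1.06 with the 5% highest doublet scores of each library removed. In smooth muscle-like cells the heat shock genes Hspa1b (1.64; 6606 and 2735 UMIs) and Hspa1a (1.52) were higher, with Igfbp2 (2.22), Abra (1.66) and Bdnf (1.51). Mrgprf (-2.32), Tnr (-1.35), Smim5 (-1.22) and Fgf14 (-1.22) were lower. In lymphatic endothelial-like cells Apod (1.41), the cell cycle inhibitor gene Cdkn1a (1.39), Marcksl1 (1.32), Serpina3n (1.19) and Plk2 (1.13) were higher. Lower there were Igfbp3 (-1.64), the circadian gene Dbp (-1.61), Tppp3 (-1.38), Plxdc2 (-1.35) and Pld5 (-1.34).

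Myeloid classes held the highest ratios of the named genes. Arg1, the arginase gene of alternatively activated macrophages, was at 7.97 in macrophage-like cells (5.48 to 13.28; 394 UMIs and 1 UMI) and at 7.19 in monocyte or dendritic-like cells (6.38 to 8.15; 1984 and 12 UMIs). Arg1 leads monocyte or dendritic-like cluster 19, which held 171 and 73 cells, while cluster 20 held 107 and 127. Spp1, the osteopontin gene, was at 2.58 and 5.85 in the same classes. Macrophage-like cells also had higher Ccl8 (2.29), which leads cluster 2 of that class, Mucl1 (2.08) and Dcstamp (1.81), and lower Ms4a1 (-3.75), Epha4 (-2.93), Slpi (-2.57) and Mzb1 (-2.07). Cluster 14 of this class, led by Top2a, Mki67 and Ighm, held 172 of 1708 macrophage-like cells in the Cept1 library and 241 of 914 in the control library. Ms4a1 and Mzb1 stand among the B and plasma cell markers, and Slpi leads mesothelial-like cluster 28. Where their UMIs in macrophage-like cells came from was not tested. Slpi and Mzb1 reversed to 2.01 and 2.10 with at least 200 genes and at most 20% mitochondrial UMIs. Slpi also reversed, to 1.67, with at least 1000 genes and at most 5% mitochondrial UMIs. Monocyte or dendritic-like cells had higher Slc7a2 (4.14), Rai14 (3.70) and Mmp14 (3.29), and lower Cxcl9 (-3.48), Stat4 (-2.18), Prg4 (-1.98), Ly6d (-1.96) and Ccl5 (-1.94). Ccl5 was at 1.78 at clustering resolution 2.

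Neutrophil-like cells came mostly from cluster 22 in the Cept1 library (126 of 133 cells) and from cluster 26, led by the immature granule genes Ngp, Camp and Ltf, in the control library (104 of 152 cells). Values of this class compare those clusters. The inflammatory genes Cxcl3 (9.02, 6.53 to 14.33; 350 UMIs and 1 UMI), Ccl3 (3.58), Wfdc17 (3.40) and Tnf (3.28) were higher in the Cept1 library. Ctla2a, which leads the unnamed cluster 30 together with platelet genes, was at 4.14. The primary granule genes Elane and Mpo had 0 UMIs there, which allows up to 4.65 CPM, against 642.1 and 337.3 CPM in the control library. Prtn3 (-6.93, -9.98 to -5.06; 2 and 361 UMIs), Fcnb (-5.07) and Col1a1 (-4.34) were also lower.

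In T or NK-like cells Ctnna2 (4.83; 192 and 16 UMIs), the platelet gene Nrgn (2.58), Pard3 (2.51), Hs3st1 (2.42) and Rab27b (2.42) were higher. The lymph node homing receptor gene Ccr7 was at -1.43, with Tbc1d30 (-1.95), Bend4 (-1.48) and Slc7a11 (-1.39). Cluster 11 of this class, led by Lef1, held 132 of 332 cells in the Cept1 library and 490 of 720 in the control library. Hs3st1 was at -0.36 with at least 200 genes and at most 20% mitochondrial UMIs per cell. In B-like cells S100a4 (2.51), Sox5 (2.31), Gem (1.52), Agbl1 (1.51) and Atrnl1 (1.38) were higher, and Gfod1 (-1.30), Nck2 (-1.21), Dhx8 (-1.20), Smad3 (-1.16) and Ndufv2 (-1.13) lower.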

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

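All tests in this part were chosen after the results they bear on had been seen. Haemoglobin genes were left out of the rankings of named genes, though their UMIs count in the totals and 4 of them stand in the list of free RNA and other cells. They made up 0.261% of the UMIs of endothelial cluster 7 in the Cept1 library and 0.044% in the control library (17887 and 1424 UMIs). Over all kept cells the haemoglobin shares were 0.416% and 0.375%. Unnamed cluster 30, which belongs to no class compared and counts among unnamed, all kept and all other cells, was led by the platelet genes Nrgn, Ppbp, Clec1b and Pf4 and held 0.674% of kept cells in the Cept1 library and 0.208% in the control library (72 and 18 cells).

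Gt(ROSA)26Sor was lower in the Cept1 library in endothelial-like cells and in most other classes. A loss of depth over this stretch of the genome is argued against by the neighbours Setd5 and Thumpd3, whose summed log2 ratio was 0.001 (-0.04 to 0.04), and recombination in endothelial cells only by the value of -2.86 (-3.06 to -2.66) outside the endothelium. An altered Rosa26 allele with a like effect in every cell failed a first test over all classes, because neutrophil-like cells were at -0.07 and monocyte or dendritic-like cells at -0.66, and the myeloid classes, set apart after that, were together at -1.70 (-1.96 to -1.46) against -4.96 (-5.43 to -4.52) in all other kept cells. For the 6 other classes such an allele stays open and was not decided, since these were grouped after their low values had been seen; the highest upper bound was that of B-like cells (-3.52, -5.81 to -1.93). Animals of another background or breeding in either group were not tested, and the labels give both groups the same floxed Cept1 genotype.

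Vegfa and adipocyte RNA were both higher in endothelial cluster 12 of the Cept1 library, with Vegfa at 1.54 and the adipocyte gene Cfd at 1636 and 234 UMIs. Free adipocyte RNA throughout the library is argued against by the 8 adipocyte markers, of which the lists hold 3 and 7 have at least 20 UMIs in endothelial-like cells, since their sum outside the endothelium was at -0.55 (-0.63 to -0.47). It stays open whether cells that carry adipocyte RNA hold the extra Vegfa, as doublets or adipocyte fragments could: without adipocyte marker UMIs Vegfa was at 0.50 (-0.55 to 1.58; 21 and 14 UMIs), and with them at 2.31 (1.45 to 3.27; 57 and 14 UMIs), so the counts are too few. Cells with such UMIs made up 28.5% of cluster 12 in the Cept1 library and 32.4% in the control library. An effect of Cept1 on Vegfa in these cells was not tested, and the gate of the sort, which bears on adipocytes and doublets, is not given in the sources used here.

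Myocd was higher in endothelial-like cells of the Cept1 library (1.99, 1.68 to 2.30), and it was also at 1.69 in fibroblast-like cells, 1.64 in macrophage-like cells and 2.60 in neutrophil-like cells. Smooth muscle RNA or doublets are argued against by the 10 smooth muscle markers. The lists hold 9 of them, and all 10 have at least 20 UMIs in endothelial-like cells. Their sum there was at 0.47 (0.42 to 0.52), and the markers moved apart. Lower were Des at -1.13 (32 and 47 UMIs), Myh11 at -0.79 and Mylk at -0.54. Higher were the abundant Acta2 at 0.73 and Tagln at 0.60, Synpo2 at 1.11, Cnn1 at 1.24 and Actg2 at 2.56 (1.07 to 4.51, from 35 and 4 UMIs). A proportional difference in the capture of Myocd across the library is argued against by its value of 0.48 (0.42 to 0.54) in smooth muscle-like cells. A source that adds Myocd UMIs to many classes stays open: in the control and Cept1 libraries the levels were 15.1 and 59.8 CPM in endothelial-like cells and 17.9 and 57.8 CPM in fibroblast-like cells, but 21.9 and 133.3 CPM in neutrophil-like cells and 47.2 and 47.7 CPM in mesothelial-like cells. No biological explanation was tested, and the gate of the sort is not given in the sources used here.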

How the results depend on the processing

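Settings that take endothelial clusters alone or with equal weight, add the shallow cluster, remove the 5% highest doublet scores or remove cells with adipocyte marker UMIs were chosen after seeing the data, as was running the other lists, the class shares and the lists outside the endothelium under them; the rest were planned. No paired analysis was possible because each group held 1 library, and leaving out a library was not possible for the same reason. Of the values of the main results under an alternative, 99 stayed within the interval of the value reported, 17 moved outside it and 5 reversed, all 5 under settings that take clusters alone or with equal weight; a value counts as reversed only if the interval of the value reported excluded 0. Ppara and Vegfa, whose intervals included 0, also turned sign: Ppara with thinned cells and, at -0.15, with equal weight per cell, and Vegfa in clusters 7 and 18 alone and, at -0.02, without cells with adipocyte marker UMIs. TMM scaling and the total without mitochondrial, ribosomal protein and haemoglobin genes shift all ratios by 1 constant, so they do not test single genes: the median log2 ratio of all genes was -0.02 as reported and 0.03 and 0.003 with them. Cept1 ranged from 0.60 to 0.85 over the planned settings, the endothelial share difference from 1.96 to 4.31 points, the phospholipid list from -0.15 to -0.06, Kdr from -0.50 to -0.18, Flt1 from -0.68 to -0.43, Gt(ROSA)26Sor from -5.77 to -4.24, Myocd from 1.35 to 3.15 and Thbs1 from 1.16 to 1.36. Among planned settings, the filter of at least 1000 genes and at most 5% mitochondrial UMIs gave an endothelial share difference of 1.96 points, the PPARα target list -0.004, VEGF signalling -0.049, Cnn1 -1.20, Snai1 0.059, Cdkn1a 0.016, the endothelial to mesenchymal list -0.002, the smooth muscle contraction list -0.52 and Slpi in macrophage-like cells 1.67. The filter of at least 200 genes and at most 20% gave Cyp2e1 -0.20, Acsl1 -0.31, Hs3st1 in T or NK-like cells -0.36, and Slpi and Mzb1 in macrophage-like cells 2.01 and 2.10. With doublets kept, Nfatc2 was at 0.38, Cxcl2 at 1.29, Ccl2 at 0.89, Egr2 at 0.12, the inflammation list at 0.01, the free RNA list at 0.19 and Slpi at 1.04. Resolution 0.5 gave Egln3 0.73; resolution 2 gave a share difference of 2.68 points, Des 0.81, Slpi 1.51, Mzb1 2.30 and Ccl5 in monocyte or dendritic-like cells 1.78. The marker gate gave Vegfa 0.44, VEGF signalling -0.024, Prkcb 0.36, Flt4 0.13, Nr1h3 0.069, Cxcl2 0.23, Actg2 -0.83 and the cell cycle list 0.007. Thinned cells gave Ppara -0.72, Acsl1 -0.27, Prkcb 0.15, Gucy1a1 0.80, Pdk1 0.11 and Des 0.82. With equal weight per cell, Adipoq was at -0.15 and Acsl1 at -0.36, and with free RNA subtracted, Lrp1 was at 0.083 and the free RNA list at 1.57. Among added settings, cells without adipocyte marker UMIs gave Cyp2e1 -0.10, the shallow cluster a share difference of 2.54 points, and removal of the 5% highest doublet scores 2.65 points, Coch in fibroblast-like cells 1.06, and Slpi and Mzb1 1.00 and 3.18. Equal cluster weights gave the PPARα target list -0.028, VEGF signalling 0.015, the Notch and arterial list -0.055, Kdr 0.23, Ereg -0.033, Alpl 0.032, Sema3g 0.069, Edn1 -0.19, Egln3 0.65, Rsad2 0.56, Irf7 0.27, Des 0.15 and Cdkn1a 0.38. Cluster 7 alone gave Ppara 2.39, Vegfa -0.30, VEGF signalling -0.024, the immediate early list 0.055, Kdr 0.055, Egfem1 0.26, Igfbp3 0.022, Acsl1 -0.043, Nfatc2 0.31, Atf4 0.09, Egln3 0.52 and Des 2.11. Cluster 12 alone gave Cept1 0.96, Vegfa 1.54, the PPARα target list 0.16, VEGF signalling 0.033, the Notch list -0.17, the smooth muscle list -0.00, lipid handling 0.066, the free RNA list 0.016, Kdr 0.19, Cxcl10 0.69, Wdr17 1.06, Lpl 0.066, Slc7a1 -0.031, Edn1 -0.56, Col1a1 0.25, Col3a1 0.35, Cyp51 0.064, Ern1 -0.17, Egln3 2.06, Pdk1 0.037, Rsad2 0.031, Cdkn1a 0.034, Stmn1 0.14 and Lrp1 0.030. Cluster 18 alone gave Cept1 0.051, Vegfa -0.59, VEGF signalling 0.19, phospholipid synthesis 0.045, the tip cell list 0.10, the Notch list -0.10, the cell cycle list 0.20, lipid handling 0.056, the free RNA list 0.16, Kdr 0.47, Flt1 0.024, Cfd -0.72, Nrg1 -1.19, Nrgn -0.075, Cxcl10 0.46, Igfbp3 0.42, Lpl 1.02, Flt4 0.63, Adm 0.059, Sema3g 1.60, Gucy1a1 0.33, Edn1 -0.24, Cnn1 -0.20, Snai1 0.28, Cycs 0.18, Uqcrc2 0.20, Atp5j 0.086, Isg15 0.63, Rsad2 5.28, Irf7 1.60, Sparcl1 0.43, Actg2 -0.72, Tyms 0.28, Cdkn1a 1.52 and Tcf15 1.31. The cause was not tested for any of these. Of the other endothelial gene values, 793 stayed within their interval, 197 moved and 24 reversed under planned settings, and 382, 185 and 61 did so under added ones. Inside cluster 7 alone 13 of 92 named genes had the opposite sign to the pooled value, inside cluster 12 alone 18 of 95 and inside cluster 18 alone 31 of 80; for 8, 16 and 26 of these the pooled interval excluded 0. For the lists outside the main results 270 stayed, 65 moved and 6 reversed under planned settings, and 95, 33 and 11 under added ones. Of the other class shares 28 stayed and 12 moved under planned settings. For named genes of the other classes 450 stayed, 87 moved and 8 reversed under planned settings; weighting, thinning, TMM and free RNA settings were not run for them. Depth limits Ppara, with 19 and 7 UMIs, and cluster 18, with 111 and 139 cells, where Cept1 had an interval from -0.39 to 0.49.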

Other observations

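The values in this part come from lists fixed in advance, but their choice among all classes was made after the values were seen, and no test between groups was run on them. Over all cells outside the endothelium, the cell cycle list was at -0.41 (-0.44 to -0.29) in the Cept1 library, with 3 of 21 members higher, but the classes went both ways. Macrophage-like cells were at -0.84, with 2 of 21 members higher, monocyte or dendritic-like cells at -0.64, with 1 of 16 higher. Neutrophil-like cells were at -1.04, within the range of matched random lists in that class (-1.10 to -0.01). T or NK-like cells were at 0.50 (0.35 to 0.56), with 21 of 21 members higher, and lymphatic endothelial-like cells at 0.20 (-0.01 to 0.35), with 9 of 11 higher. The T or NK value also compares clusters, since cluster 11 held 132 of 332 cells in the Cept1 library and 490 of 720 in the control library, and cluster 27 held 69 and 38. So does the macrophage value, since cluster 14, led by Top2a and Mki67, held 172 of 1708 macrophage-like cells in the Cept1 library and 241 of 914 in the control library. Sterol and fatty acid synthesis genes, which make cholesterol and fatty acids, were at -0.26 (-0.30 to -0.20) in all cells outside the endothelium. Of 32 members 6 were higher. The value pools classes whose shares differ between the libraries. B-like cells were at -0.50, neutrophil-like cells at -0.46 and macrophage-like cells at -0.265. The neutrophil value was within the range of matched random lists in that class (-1.10 to 0.01). Smooth muscle-like cells were at -0.15, fibroblast-like cells, the largest class, at -0.12 and monocyte or dendritic-like cells at -0.05. T or NK-like cells were at 0.002 and lymphatic endothelial-like cells at 0.08. In monocyte or dendritic-like cells the glycolysis and hypoxia list was at 0.80 (0.66 to 0.97). Of 23 measured members 18 were higher, Vegfa at 1.21 among them. The Arg1 and Spp1 values of that class are given above. Cluster 19, led by Arg1, held 171 and 73 cells of this class and cluster 20 held 107 and 127, so its values also compare those clusters.

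In T or NK-like cells many lists were higher in the Cept1 library. The Notch and arterial list was at 2.32 (1.89 to 2.5), with 16 of 16 members higher, the shear response and nitric oxide list at 1.41, with 16 of 19 higher, and the endothelial inflammation list at 1.09, with 18 of 19 higher. The immediate early list was at 0.88, the tip cell list at 0.82 (19 of 23 higher), extracellular matrix at 0.80 (24 of 26), the endothelial to mesenchymal list at 0.48, smooth muscle contraction at 0.44 (13 of 14) and VEGF signalling at 0.31 (35 of 42). Closer to 0 were PPARα targets at 0.09, oxidative phosphorylation at -0.02 and the list of free RNA and other cells at 0.14. This last list holds no endothelial genes, so it does not bear on RNA of endothelial cells. In macrophage-like cells the Notch and arterial list was at -0.84, with 2 of 18 members higher. It was not alone: extracellular matrix was at -0.72 (2 of 28 higher), smooth muscle contraction at -0.55 (2 of 16) and shear response at -0.42 (3 of 19). The endothelial to mesenchymal list was at -0.41 (3 of 22) and the tip cell list at -0.41 (7 of 29). PPARα targets were at -0.01 and the interferon list was higher, at 0.34 (22 of 25). Whether RNA of other cells enters these values was not tested. In neutrophil-like cells, which came mostly from different clusters in each library, the extracellular matrix list was at -1.85, with 3 of 23 members higher, and the list of free RNA and other cells at -1.77, with 0 of 16 higher.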
